A study of Caenorhabditis elegans with 6 samples.

How the data were processed

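Total RNA of Caenorhabditis elegans was extracted with TRIzol, treated with DNase I and made into standard Illumina libraries, per the labels' protocols, and only RNA above a minimum of integrity was used. The deposited table holds TPM values (a transcript abundance scaled by the authors for gene length and to a fixed total per library) for 46778 genes in 1 column per library, rounded to 2 decimals. Per the submitters' processing notes, fastp, HISAT and RSEM were used with the genome build WBcel235. The tool versions, the annotation release, the filters and the strand setting were not given in the sources used here. The TPM unit was read from the deposited values, since each column sums to between 996560 and 997390 and the smallest values fall with gene length. TPM is a share of a fixed total, so a large change in abundant transcripts shifts the values of all others, and the division of reads between near-identical copies depends on the model that assigned them. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be told apart.

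Gene symbols and coordinates were taken from the Ensembl annotation of WBcel235, which is the build in the processing notes. A symbol was found for 43818 of the 46778 gene identifiers and for 12224 of the 12590 tested genes, and 46603 identifiers were in the annotation. Of the tested genes, 12072 were protein-coding, and 21 repeated the values of an earlier row in all 6 libraries, where the first row of each such set is not counted. Of the 50 changed genes, 10 overlap another annotated gene at or above 1 TPM. Read counts were not used here. In TPM, 1 fragment has about the same worth in all transcripts of the same length, and the most frequent low value of genes with a single transcript of 300 to 1500 bp was used to estimate what 1 fragment was worth, 0.0500 to 0.0521 TPM for 1 kb. The most frequent value in a second, higher range was 1.85 to 1.98 times the first. Both values were sought within preset ranges that largely fix this ratio, so it does not check the estimate. The estimate of 21610000 to 22760000 fragments per library rests on the first value and on the deposited TPM values. By this unchecked estimate, a gene at 1 TPM with 1 kb of transcript rests on about 20 fragments.

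Samples were grouped by their titles into Control and HLB01, 3 each. The labels record no batch, day or plate. Values were tested as log2(TPM + 1) in limma 3.58.1 under R 4.3.3, with a mean-variance trend, for genes with at least 1 TPM in at least 3 libraries. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are given as log2 differences of the fitted means with their SE, and folds without a log2 scale are ratios of mean TPM. No fold is given for genes listed at 0 in all libraries of a group.

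Before the data were examined, 49 gene lists, the design and the rule for named genes were fixed. Of the lists, 47 had at least 3 tested genes, and 11 names in the lists matched no gene symbol. Sequence names among these were then looked up by transcript name, which gave sysm-1. The list of mitochondrially encoded genes was filled with the protein-coding genes of the mitochondrial genome in place of its fixed symbols. The lists of adult-stage collagens (1 gene tested) and coelomocyte markers (0 genes tested) were not tested as lists. Lists were tested with camera in limma with a preset correlation of 0.01, adjusted over the 47 lists, and again with an estimated correlation and with fry. The named genes are the 8 higher and 8 lower genes with the largest absolute log2 fold change among those past the threshold, with no overlap of the groups and a mean of at least 5 TPM in the higher group; up to 4 members with the smallest p past the threshold from each passing list and from the lists of cuticle collagens, DAF-16 activated targets, heat shock proteins, antioxidant enzymes and SKN-1 targets, or the member with the smallest p if none passed; and daf-16, skn-1, hsf-1, daf-2, sod-3, gst-4, hsp-16.2, mtl-1, col-19 and emb-9 whatever their test. Genes named outside this rule are stated to have been chosen after their values were seen, apart from partners named for an overlap or as a copy.

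The test was checked on simulated data for this comparison, with 200 of the 12590 genes changed in each of 20 simulations. It recovered 36.0% of genes with a log2 change of 0.40, 70.5% with 0.80 and 91.7% with 1.60, and 5.27% of its calls were unchanged genes. With no gene changed, it called 2 genes and 1 list over the 20 simulations together. Genes were simulated independently of each other, whereas the estimated correlation within a list reached 0.84 in the data. The simulated count of lists therefore does not cover correlated genes, and other splits of the 6 libraries, each of which mixes both groups, gave 6 to 18 lists.

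Alternatives fixed beforehand were limma without the trend, array weights, quantile normalization, scaling to a common median, no filter, a filter of 5 TPM, pseudocounts of 0.1 and 5, stricter thresholds, the replicate number as a block, each library left out in turn, camera with an estimated correlation, and fry. Removal of each library's trend with gene length, TPM rescaled to nuclear protein-coding genes, identical copies counted once, and further settings of the list test were added after the data were seen.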

Results

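RNA from the nematode Caenorhabditis elegans was sequenced in 6 libraries, 3 from control animals and 3 from animals treated with HLB01. HLB01 is known here only by this code name; the series title concerns a root extract of the plant Vicatia thibetica, ageing, collagen and stress resistance. The dose, the duration and the stage of the animals were not given in the sources used here. The agent field of the labels reads HLB01, HLB02 and HLB03 for the 3 treated libraries, whereas their titles and the study design describe 3 replicates of HLB01, and the grouping follows the titles. The labels record no batch, day or temperature, and they do not say whether the replicates were separate cultures, so p-values measure only the spread between these samples.

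Expression was given in TPM, a transcript abundance scaled for gene length and to a fixed library total, for 46778 genes. Of these, 26293 were listed at 0 in all 6 libraries. Read counts were not used here. The most frequent low value of each library, sought within a preset range, gave an unchecked estimate of 21610000 to 22760000 fragments per library. By this estimate, 1 TPM was worth 19.2 to 20.01 fragments for a transcript of 1 kb. The 12590 genes at or above 1 TPM in at least 3 libraries were tested. Over these genes, the log2(TPM + 1) values correlated at 0.984 to 0.988 within the groups and at 0.980 to 0.988 between them. HLB01 replicate 3 stood apart from the other 5 libraries on the first principal component, which held 31.3% of the variance, with a score of 32.01 against -15.3 to -0.57. Ribosomal RNA took 2684, 1223 and 530 TPM in the Control libraries and 2123, 2467 and 4895 TPM in the HLB01 libraries, with the highest value in HLB01 replicate 3.

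The comparison of HLB01 with Control asks which transcripts differed in treated animals. Of 19 tested heat shock and chaperone genes, 7 were lower in HLB01 animals, by 2.19-fold to 3.69-fold in TPM. Also lower were the lysozyme gene ilys-5 (1.92-fold), the nuclear hormone receptor gene nhr-17 (2.64-fold) and the yolk protein gene vit-4 (1.37-fold). Higher in HLB01 animals were the glutathione S-transferase genes gst-35 and gst-21, the UDP-glucuronosyltransferase gene ugt-3, the fatty acid desaturase gene fat-5 and the fatty acid and retinol-binding protein gene far-3, by 1.84-fold to 3.84-fold. In limma with a mean-variance trend and Benjamini-Hochberg adjustment, 50 genes changed at an adjusted p below 0.05, 21 of them higher and 29 lower. The 3 HLB01 values lay outside the 3 Control values for all 50, and for 13.8% of all tested genes, where chance gives 10%. The test on these same values favours genes without overlap, so this is not separate support for the 50. The median absolute log2 fold change of the 50 genes was 0.85, and 16 of them reached 1, 4 higher and 12 lower. Fold changes on this scale understate the change of genes with low TPM. An unadjusted p below 0.05 was reached by 1047 genes, where 629.5 would be expected with no change. Other splits of the 6 libraries into 3 and 3, each of which mixes both groups, gave 283 to 878. The count of changed genes fell to between 19 and 32 when any 1 of the 6 libraries was left out. It was 26, 19 and 24 genes without Control replicates 1, 2 and 3, and 25, 32 and 24 genes without HLB01 replicates 1, 2 and 3. It also depended on the model and the filter, with 27 genes in limma without the trend, 80 with array weights and 22 with no filter on low values.

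Among the heat shock proteins and cytosolic chaperones, 7 of 19 tested genes fell and none rose, and 10 fell when p-values were adjusted over the list alone. The gene hsp-70 (WBGene00002026, WBcel235 chromosome I, 9320325 to 9322519), which encodes a heat-inducible cytosolic chaperone, went from 18.0 ± 1.19 TPM in Control to 4.89 ± 0.525 TPM in HLB01 (mean ± SD, n = 3 each), a log2 fold change of -1.69 ± 0.10 (SE; limma adjusted p = 0.00224). Its relative F44E5.5 (WBGene00009692, chromosome II, 11759662 to 11761861) went from 93.0 ± 7.18 to 28.6 ± 4.95 TPM (log2 fold change -1.68 ± 0.12, limma adjusted p = 0.00459). The small heat shock protein gene hsp-16.1 (WBGene00002017, chromosome V, 9090077 to 9090604) had the highest level of the 7, at 341 ± 36.2 TPM in Control and 139 ± 15.8 TPM in HLB01 (log2 fold change -1.29 ± 0.10, limma adjusted p = 0.00614). For hsp-16.41, hsp-16.2 and both copies of hsp-16.48 the log2 fold changes were -1.25 ± 0.13, -1.08 ± 0.13 and -1.13 ± 0.13, with limma adjusted p = 0.0168, 0.0256 and 0.0228. The 12 other members had a median log2 fold change of -0.03 and a mean of -0.17. They include F44E5.4, at 43.8 ± 11.7 and 15.1 ± 5.78 TPM (log2 fold change -1.50 ± 0.27, limma adjusted p = 0.0973), hsp-110 (-0.14 ± 0.04) and hsp-25 (-0.17 ± 0.06), the 3 added when adjusted over the list alone and named here after their values were seen. The gene hsf-1, which encodes the transcription factor that activates heat shock genes, was at 51.8 ± 1.80 and 51.95 ± 1.19 TPM (log2 fold change 0.00 ± 0.05, limma adjusted p = 0.986).

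Several of these genes have near-identical copies, between which reads cannot be divided with certainty. The 2 copies of hsp-16.48 carried the same values in every library, and the second copy of hsp-16.1 was listed at 0 in all libraries. The summed TPM of F44E5.4 and F44E5.5 was 137 ± 12.8 in Control and 43.7 ± 8.19 in HLB01, 3.13-fold lower. The calls of hsp-70, F44E5.5 and hsp-16.1 held when each library was left out. The call of hsp-16.41 was lost without Control replicate 1 or 2 or HLB01 replicate 2 or 3 (limma adjusted p up to 0.107). That of hsp-16.2 was lost without Control replicate 1 or 2 or HLB01 replicate 1 or 3 (up to 0.112), and that of hsp-16.48 without any 1 Control library or HLB01 replicate 3 (up to 0.112).

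**Figure D1:**
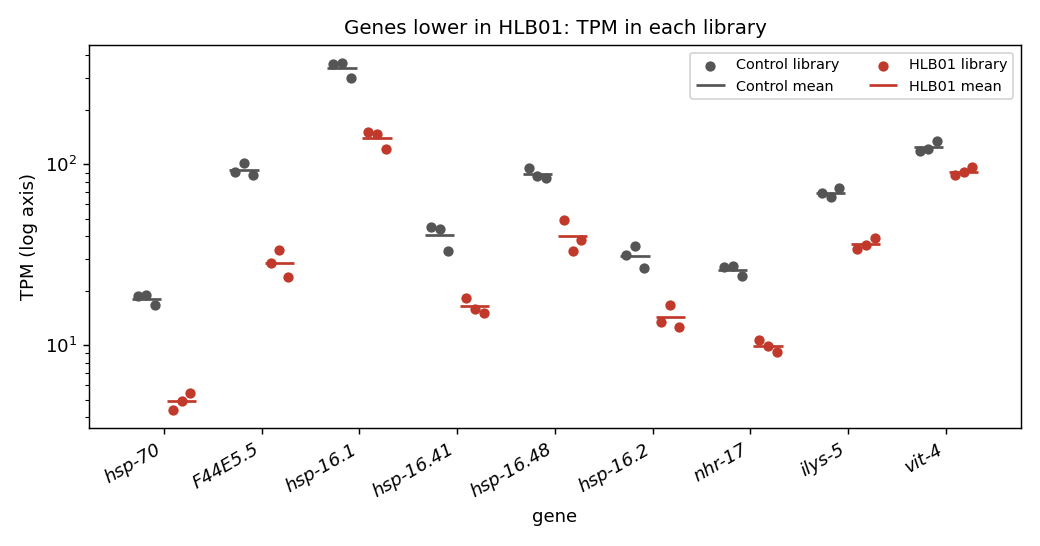
TPM (log axis) of 9 genes that were lower in HLB01, with 1 point per library and a line at the mean of each group of 3. The 3 HLB01 points of each gene lie below its 3 Control points, for hsp-70 between 4.36 and 5.41 TPM against 16.7 to 18.8 TPM.

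Some genes of detoxification enzymes were among those that rose. None of 38 tested cytochrome P450 genes passed over all genes, with 21 positive and 17 negative log2 fold changes (camera adjusted p = 0.597). When adjusted over that list alone, 2 were higher and 2 lower. Nor did any of 26 tested ABC drug transporter genes pass over all genes (camera adjusted p = 0.940), and 1 was lower when adjusted over the list alone. Among the glutathione S-transferases, 2 of 35 tested genes rose and none fell, and 6 rose when adjusted over the list alone. The gene gst-35 (WBGene00001783, chromosome II, 15183807 to 15185389) went from 18.3 ± 3.10 to 53.0 ± 2.31 TPM (mean ± SD, n = 3 each; log2 fold change 1.49 ± 0.11, limma adjusted p = 0.00505). The gene gst-21 went from 1.36 ± 0.182 to 5.22 ± 1.42 TPM, a 3.84-fold difference (limma adjusted p = 0.0404). Among the UDP-glucuronosyltransferases, which attach a sugar acid to foreign compounds, 1 of 42 tested genes rose, and 3 rose and 1 fell when adjusted over the list alone. The gene that rose was ugt-3 (WBGene00013903, chromosome V, 12798308 to 12800271), from 7.37 ± 0.210 to 17.8 ± 0.887 TPM (log2 fold change 1.17 ± 0.07, limma adjusted p = 0.00258). Outside the gene lists, the catechol-O-methyltransferase family gene comt-5 rose from 24.1 ± 3.43 to 45.8 ± 2.24 TPM (limma adjusted p = 0.0193). The gene ZK742.3, also outside the lists, rose from 2.90 ± 0.162 to 6.60 ± 1.08 TPM (limma adjusted p = 0.0396). It overlaps xpo-1 on the other strand, at 139 TPM in Control and 138 TPM in HLB01. The calls of gst-35 and ugt-3 held when each library was left out. The genes gst-21 and ZK742.3 kept theirs only without HLB01 replicate 2, and comt-5 only without Control replicate 2 or 3, with limma adjusted p up to 0.179, 0.155 and 0.0911 otherwise.

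None of the 12 tested targets of SKN-1, the transcription factor of the oxidative stress response, passed the test over all genes, and 3 were higher when adjusted over the list alone. As a list they were higher in HLB01 (median log2 fold change 0.12, camera adjusted p = 0.00169, adjusted p = 0.459 with an estimated correlation). The member with the smallest p was ugt-13, at 1.83 ± 0.0656 TPM in Control and 3.39 ± 0.445 TPM in HLB01 (limma adjusted p = 0.12), and gst-4 was at 10.3 ± 0.954 and 14.1 ± 1.40 TPM (limma adjusted p = 0.238). As lists, the UDP-glucuronosyltransferases (median log2 fold change 0.08, camera adjusted p = 0.00508, adjusted p = 0.534 with an estimated correlation) and the glutathione S-transferases (median 0.05, camera adjusted p = 0.0172, adjusted p = 0.932 with an estimated correlation) were also higher. The list of SKN-1 targets includes members of both families, among them gst-4 and ugt-13, so these lists are not separate evidence. The call of the SKN-1 targets was lost without HLB01 replicate 1 (camera adjusted p = 0.0591), where their median log2 fold change was 0.03. It was 0.20 without Control replicate 1 and 0.19 without HLB01 replicate 3. The median of the UDP-glucuronosyltransferases was 0.05 without Control replicate 2, 0.03 with a pseudocount of 5 and 0.14 with a filter of 5 TPM. That of the glutathione S-transferases was 0.02 without HLB01 replicate 1 and 0.09 without HLB01 replicate 2. Those of the other 2 lists were lost without Control replicate 1 (0.110 and 0.452) or HLB01 replicate 1 (0.0824 and 0.317), and that of the glutathione S-transferases also with no filter on low values (0.138). The genes skn-1 (log2 fold change -0.04 ± 0.05, limma adjusted p = 0.887) and mtl-1, a metallothionein gene (0.09 ± 0.10, limma adjusted p = 0.866), did not pass.

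Both lists of fatty acid metabolism genes were higher in HLB01 in the test with a preset correlation. Among 20 tested genes of fatty acid synthesis and desaturation, 1 rose over all genes and 5 rose when adjusted over the list alone. Of the 20, 17 had a positive log2 fold change (median 0.12, camera adjusted p = 6.59e-06, adjusted p = 0.459 with an estimated correlation). The gene that rose, fat-5 (WBGene00001397, chromosome V, 17725004 to 17726818), encodes a desaturase of palmitic acid and went from 43.9 ± 3.73 to 80.7 ± 4.56 TPM (mean ± SD, n = 3 each; log2 fold change 0.87 ± 0.07, limma adjusted p = 0.00614). Among 39 tested genes of lipolysis and beta-oxidation, acox-1.1, a peroxisomal acyl-CoA oxidase gene, rose 1.30-fold, from 33.99 ± 0.751 to 44.2 ± 0.860 TPM (limma adjusted p = 0.0321), and 2 genes rose when adjusted over the list alone. That list was higher as a whole (median log2 fold change 0.09, camera adjusted p = 0.000401, adjusted p = 0.459 with an estimated correlation). Outside these lists, far-3 (WBGene00001387, chromosome V, 12996787 to 12997522) rose from 71.2 ± 2.41 to 134 ± 7.48 TPM (log2 fold change 0.91 ± 0.05, limma adjusted p = 0.00224), and cpt-3, of the carnitine palmitoyltransferase family, rose from 3.05 ± 0.138 to 6.83 ± 0.662 TPM (limma adjusted p = 0.0177). The calls of acox-1.1 and cpt-3 were each lost when any 1 library was left out, with limma adjusted p up to 0.145 and 0.109. On the other strand, far-3 overlaps far-5, at 7.96 and 5.64 TPM, and fat-5 overlaps twk-42, at 1.27 and 1.24 TPM.

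**Figure D2:**
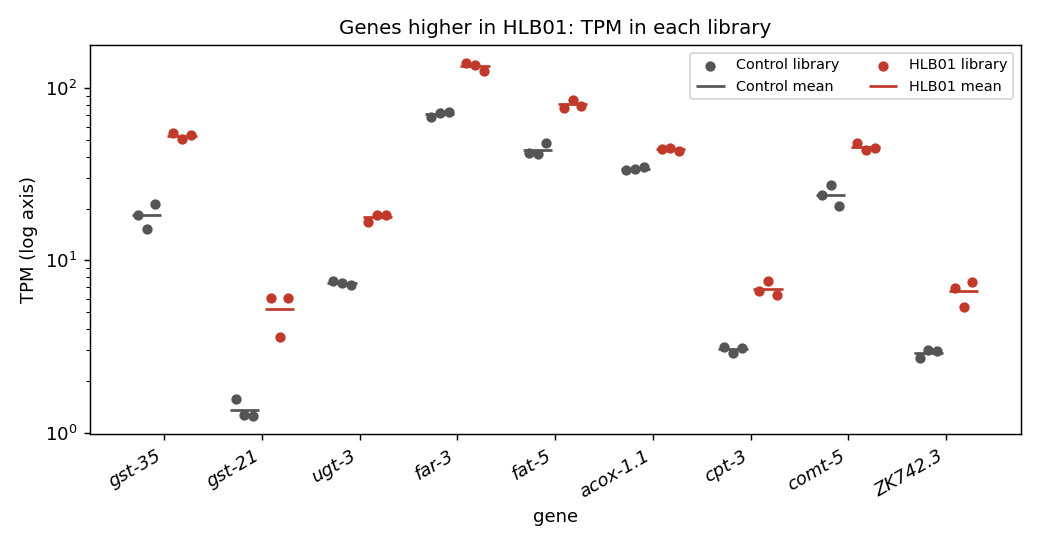
TPM (log axis) of 9 genes that were higher in HLB01, with 1 point per library and a line at the mean of each group of 3. The 3 HLB01 points of each gene lie above its 3 Control points, for gst-35 between 50.5 and 55.1 TPM against 15.2 to 21.4 TPM.

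All 6 vitellogenin genes, which encode yolk proteins made in the intestine, had a negative log2 fold change. Over all genes tested 1 of them fell, and 4 fell when adjusted over the list alone. The list was lower in HLB01 (median log2 fold change -0.37, camera adjusted p = 3.03e-07, adjusted p = 0.459 with an estimated correlation). The estimated correlation between its genes was 0.84, so they do not count as independent. The gene vit-4 (WBGene00006928, chromosome X, 3558769 to 3563965) went from 125 ± 8.10 to 91.1 ± 4.61 TPM (mean ± SD, n = 3 each), 1.37-fold lower (log2 fold change -0.45 ± 0.06, limma adjusted p = 0.0392). That call was lost when any 1 library was left out, with limma adjusted p up to 0.155, and vit-4 overlaps F59D8.3 on the other strand, at 9.12 and 13.3 TPM. Markers of the intestine (13 tested, median log2 fold change -0.03, camera adjusted p = 0.444) and of oocytes and germline (26 tested, median 0.01, camera adjusted p = 0.849) did not pass, although 1 intestinal marker was higher and 4 were lower when adjusted over the list alone. Early embryo markers did not pass (25 tested, 19 with a negative log2 fold change, median -0.12, camera adjusted p = 0.0910). The call of the sperm markers, given below, was lost with an estimated correlation (adjusted p = 0.949). Relative to the Control mean, the vitellogenins were lowest in HLB01 replicate 1 (-0.55), as were the sperm and muscle markers. Without it the vitellogenin median was -0.28.

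The lysozyme genes and the genes of an immune signalling pathway were lower as lists in the same test. The saposin-like proteins did not pass as a list (22 tested, median log2 fold change -0.01, camera adjusted p = 0.839). None of them passed over all genes, and 5 were higher and 2 lower when adjusted over the list alone. The C-type lectins and the epidermal antimicrobial peptides, given below, did not pass as lists either. Of 12 tested lysozyme genes, 1 fell over all genes and 4 fell when adjusted over the list alone. The list was lower in HLB01 (median log2 fold change -0.22, camera adjusted p = 0.000256, adjusted p = 0.459 with an estimated correlation). The gene that fell was ilys-5 (WBGene00017691, chromosome X, 6533490 to 6536840), an invertebrate-type lysozyme, from 69.7 ± 4.18 to 36.3 ± 2.69 TPM (mean ± SD, n = 3 each; log2 fold change -0.92 ± 0.07, limma adjusted p = 0.00505). In the list of the p38 immune pathway and its targets none of 12 tested genes passed over all genes, and 2 were lower when adjusted over the list alone. The list was lower (median log2 fold change -0.15, camera adjusted p = 0.00169, adjusted p = 0.459 with an estimated correlation). The median was -0.09 with a pseudocount of 5 and -0.19 with a pseudocount of 0.1. Relative to the Control mean, the list was at -0.12, -0.14 and -0.24 in HLB01 replicates 1, 2 and 3. The list member with the smallest p was sysm-1, at 139 ± 12.4 and 96.9 ± 9.32 TPM (limma adjusted p = 0.0844). Among 143 tested nuclear hormone receptor genes only nhr-17 (WBGene00003616, chromosome X, 12663837 to 12667854) passed over all genes or when adjusted over the list alone, falling from 26.2 ± 1.92 to 9.93 ± 0.760 TPM (log2 fold change -1.31 ± 0.09, limma adjusted p = 0.00258). It overlaps nlp-76 on the same strand, at 5.12 and 5.26 TPM. The long non-coding RNA linc-53 was at 4.92, 15.2 and 4.61 TPM in the Control libraries and listed at 0 in the HLB01 libraries (limma adjusted p = 0.0324). The calls of ilys-5 and nhr-17 held when each library was left out, and that of linc-53 held only without Control replicate 2, with limma adjusted p up to 0.132 otherwise.

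Cuticle collagen genes showed no common shift between the groups. Of 176 such genes, 117 lay below the filter on low values, and of the 59 tested none changed over all genes in limma or when adjusted over the list alone, with 4 at an unadjusted p below 0.05. Their log2 fold changes ran from -0.57 to 0.68, 27 positive and 32 negative, with a median of -0.01 and a mean of 0.02 (camera adjusted p = 0.953). The member with the smallest p was col-96, at 22.7 ± 0.837 TPM in Control and 15.1 ± 2.65 TPM in HLB01 (mean ± SD, n = 3 each; limma adjusted p = 0.160). The adult cuticle collagen gene col-19 was at 84.8 ± 6.54 and 90.6 ± 8.31 TPM (log2 fold change 0.09 ± 0.08, limma adjusted p = 0.830), and emb-9, a type IV collagen gene of basement membranes, was at 23.9 ± 1.95 and 22.9 ± 3.39 TPM (log2 fold change -0.07 ± 0.11, limma adjusted p = 0.912). The lists of basement membrane and matrix proteins (16 tested, camera adjusted p = 0.940) and of collagen processing and cross-linking (11 tested, camera adjusted p = 0.839) did not pass either. The median SE of a tested cuticle collagen gene was 0.14 on the log2 scale, against 0.10 for all tested genes.

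Of 15 tested genes that the insulin pathway transcription factor DAF-16 activates, 1 rose both over all genes and when adjusted over the list alone. It was fat-5, the fatty acid desaturase gene. The list had a median log2 fold change of -0.07 and a mean of 0.02, and camera ranked it as lower (adjusted p = 0.784). None of 26 tested antioxidant enzyme genes changed in limma over all genes or over the list alone (median log2 fold change 0.02, camera adjusted p = 0.839), with the smallest p for the catalase gene ctl-1, at 116 ± 1.74 and 107 ± 5.17 TPM (limma adjusted p = 0.551). The superoxide dismutase gene sod-3 was at 2.41 ± 0.142 and 2.25 ± 0.455 TPM (log2 fold change -0.08 ± 0.14, limma adjusted p = 0.916). The genes daf-16 (-0.09 ± 0.05, limma adjusted p = 0.695) and daf-2, the insulin receptor gene (0.03 ± 0.07, limma adjusted p = 0.952), did not pass, and none of 23 tested longevity regulators did.

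The remaining lists past the threshold had no member that passed over all genes, and their 3 HLB01 means overlapped the 3 Control means. Of the 12 mitochondrially encoded protein genes, 11 had a positive log2 fold change and 3 were higher when adjusted over the list alone (median 0.21, camera adjusted p = 9.60e-05, adjusted p = 0.534 with an estimated correlation). Relative to the Control mean, the list was at 0.26, 0.01 and 0.09 in HLB01 replicates 1, 2 and 3, and without HLB01 replicate 1 its median was 0.13. The member with the smallest p, WBGene00010960, was at 58.3 ± 2.23 and 74.4 ± 5.27 TPM (limma adjusted p = 0.105). The 81 tested cytosolic ribosomal protein genes were higher by a median log2 fold change of 0.03 (camera adjusted p = 0.00565, adjusted p = 0.932 with an estimated correlation), with rpl-29 at 6854 ± 24.7 and 7499 ± 190 TPM (limma adjusted p = 0.432). The 59 tested sperm markers (median -0.14, camera adjusted p = 0.00565, adjusted p = 0.949 with an estimated correlation) and the 15 tested body wall muscle markers (median -0.12, camera adjusted p = 0.0168, adjusted p = 0.949 with an estimated correlation) were lower. Their members with the smallest p were msp-45, at 19.5 ± 2.61 and 14.9 ± 2.42 TPM (limma adjusted p = 0.519), and act-4, at 182 ± 10.5 and 155 ± 11.9 TPM (limma adjusted p = 0.350). For these 3 lists no gene passed when adjusted over the list alone. Relative to the Control mean, the sperm markers were at -0.40, 0.17 and -0.21 and the muscle markers at -0.25, -0.21 and 0.09 in HLB01 replicates 1, 2 and 3. The ribosomal protein call was lost without Control replicate 1 (camera adjusted p = 0.216) or HLB01 replicate 3 (0.306), each with a median of 0.02. The sperm marker call was lost without Control replicate 3 (0.174), HLB01 replicate 1 (0.752) or HLB01 replicate 3 (0.0607), and the muscle marker call without Control replicate 1 (0.0503), Control replicate 3 (0.0691), HLB01 replicate 1 (0.317) or HLB01 replicate 2 (0.389). The sperm median was -0.24 and -0.05 without Control replicates 1 and 3, and -0.03 and -0.33 without HLB01 replicates 1 and 2. The muscle median was -0.04, -0.05 and -0.27 without HLB01 replicates 1, 2 and 3.

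In all, 13 of 47 gene lists with at least 3 tested genes passed camera, 7 higher and 6 lower, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment. Some of these lists share genes, as the SKN-1 targets do with the glutathione S-transferases. The heat shock list had the smallest p (median log2 fold change -0.17, mean -0.59, camera adjusted p = 3.82e-12, adjusted p = 0.459 with an estimated correlation). It was the only list to pass fry, which tests whether the genes of a list move one way on balance (adjusted p = 0.0260). With an estimated correlation none of the 47 lists passed. Other splits of the 6 libraries into 3 and 3, each of which mixes both groups, gave 6 to 18 lists with the preset correlation. In 9 of the 13 lists the 3 HLB01 means lay outside the 3 Control means. These same 9 make up the 19.1% of the 47 lists without overlap, where chance gives 10%. The 13 lists were chosen on these same libraries, so the lack of overlap is not separate support. An exact permutation test of 3 against 3 cannot give a p below 0.1. The other lists did not pass, with camera adjusted p from 0.0614 for the histone genes to 0.953 for the cuticle collagens.

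**Figure D3:**
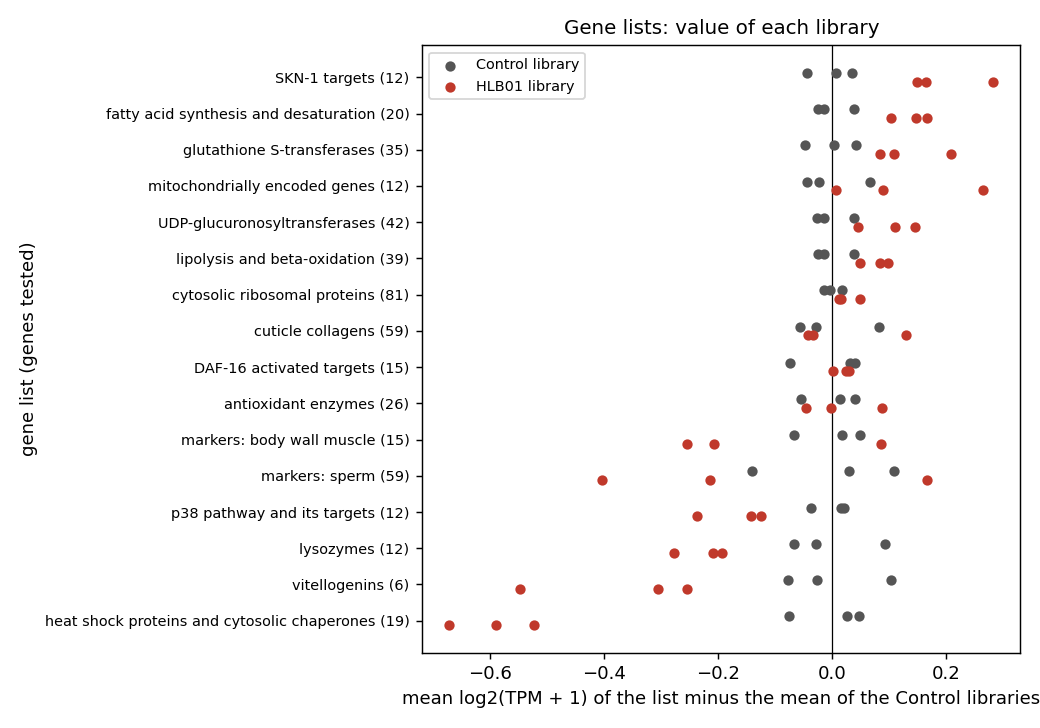
Mean log2(TPM + 1) over the tested genes of 16 gene lists, minus the mean of the Control libraries, with 1 point per library. The heat shock list lay between -0.67 and -0.52 in the HLB01 libraries and between -0.07 and 0.05 in the Control libraries, and the sperm markers lay between -0.40 and 0.17 in the HLB01 libraries and between -0.14 and 0.11 in the Control libraries.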

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

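Tests on gene length, on the genes in the TPM total and on identical copies, and the list tests with quantile normalization, other pseudocounts or a filter of 5 TPM, were chosen after the data were seen. The genes hsp-70, F44E5.5, hsp-16.1, nhr-17, ilys-5, gst-35, ugt-3, fat-5 and far-3 kept their direction and their call under all 18 alternatives other than the stricter thresholds, hsp-70 with a log2 fold change from -1.87 to -1.22 and far-3 from 0.87 to 0.95. Over all called named genes and all alternatives, now with the stricter thresholds, which lose calls by construction, 293 values kept the call, 103 lost it and 0 changed direction. From 50 genes (21 higher, 29 lower), the count moved to 27 (11 and 16) without the trend, of which 24 were shared, to 80 (33 and 47) with array weights, which kept all 50, and to 22 (9 and 13) with no filter, of which 20 were shared; the causes were not tested. The stricter thresholds, which by construction call fewer genes, gave 16 (4 and 12) at an absolute log2 fold change of 1 and 13 (6 and 7) at an adjusted p below 0.01. Leaving out 1 library, which leaves fewer samples, gave 19 to 32 genes, 8 to 12 higher and 11 to 23 lower. The other settings gave 46 to 69 genes. Of the 13 lists, 0 passed camera with an estimated correlation and 1 passed fry; leaving out 1 library kept 8 to 13 of them, with 9 to 15 passing among all 47 lists. Among genes that were not called, sysm-1 passed with array weights and with the replicate block (limma adjusted p down to 0.0264), whereas hsf-1 had a log2 fold change of -0.0044 with array weights and of -0.023 to 0.024 with 1 library left out, and leave-one-out ranges crossed 0 for mtl-1 (-0.035 to 0.155), daf-2 (-0.041 to 0.072), emb-9 (-0.168 to 0.038) and sod-3 (-0.176 to 0.027). Whether the replicate numbers pair the samples was not settled. The deviations from the group means of same-numbered libraries correlated at -0.013, 0.038 and 0.127, and those of differently numbered libraries at -0.158 to 0.142. These values show no clear pairing over all genes, but they cannot exclude a batch that affects some genes. By these deviations, 2 of the 3 HLB01 and 1 of the 3 Control libraries correlated best with their own number. With the replicate block, 48 genes changed (17 higher, 31 lower), 35 of them shared, and 14 lists passed. The estimated depth leaves genes near 1 TPM with about 20 fragments per kb.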

Other observations

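Other genes past the threshold fall outside the groups described above. Apart from comt-5, which the rule for named genes gave and which is repeated here as a neighbour, they were chosen after their values were seen. The neighbouring genes comt-4 (chromosome V, 2049217 to 2050185) and comt-5 (2052226 to 2053609), of the catechol-O-methyltransferase family, were both higher in HLB01, comt-4 from 218 ± 8.62 to 375 ± 12.06 TPM (mean ± SD, n = 3 each; log2 fold change 0.78 ± 0.04, limma adjusted p = 0.00224) and comt-5 by 1.90-fold. Lower in HLB01 were the ceramidase gene asah-2, at 69.97 ± 6.94 and 41.5 ± 2.35 TPM (limma adjusted p = 0.0177), and the sphingosine phosphate lyase gene spl-2, at 9.56 ± 0.761 and 5.18 ± 0.09 TPM (limma adjusted p = 0.0224). The gene irg-1 (1.63-fold), the caenacin gene cnc-2 (2.102-fold), the C-type lectin gene clec-71 (1.55-fold) and the galectin gene lec-10 (1.46-fold) were lower, whereas the lectin gene clec-52 was higher (1.38-fold), with limma adjusted p from 0.00614 to 0.0353. The transcription factor gene ets-4 was higher, at 13.7 ± 0.263 and 21.7 ± 2.11 TPM (limma adjusted p = 0.0365), and it overlaps ceh-60 on the other strand, at 6.38 and 5.97 TPM. The list of C-type lectins, which holds clec-52 and clec-71, did not pass (75 tested, 1 higher and 1 lower, 5 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.656). Nor did the list of epidermal antimicrobial peptides, which holds cnc-2 (16 tested, 1 lower, also over the list alone, camera adjusted p = 0.487). The other genes here were not tested as a group.

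For the patterns below, the tests of shared reads, single libraries, harvest conditions, intestinal RNA, germline and stage were chosen after the results were seen, and the removal of the length trend was added after the data were seen; the count over other splits was set beforehand.

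The lower heat shock genes are a pattern in which the 7 called members had a mean log2 fold change of -1.32 and the 12 others a mean of -0.17. Of these 12, 3 were lower when adjusted over the list alone. The call in these same data made this division, so the 2 means are not a test of a difference. The 7 include 2 copies of hsp-16.48 with the same values, and the 12 include F44E5.4, whose log2 fold change lay within the range of the 7. Reads moving between near-identical copies would leave the sum of a pair unchanged, but the summed TPM of F44E5.4 and F44E5.5 had a log2 difference of -1.64, which argues against this cause for that pair. A single library does not carry the pattern, since the mean of all 19 genes, -0.594, stayed between -0.631 and -0.556 whichever library was left out. A difference in temperature, handling or harvest between the groups could also lower these genes, and it cannot be told apart from HLB01 because 0 label fields record a batch, day, time, temperature or plate. An effect of HLB01 itself was not tested apart from this, which would need cultures with recorded temperature and harvest.

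The slightly higher ribosomal protein genes and the lower body wall muscle genes differ in length, with median exonic lengths of 530 and 1719 bp against 1302 bp over all tested genes. Gene length bias is argued against as the whole cause, since after each library's trend with length was removed the smaller remaining share of the list differences was 0.888, for muscle, the ribosomal difference grew from 0.026 to 0.044, and both lists still passed camera (adjusted p = 0.00130 and 0.0207). With this removal the median log2 fold change over all tested genes also moved, from -0.0038 to 0.0085, so part of both changes was common to all genes. Before it, log2 fold change and exonic length had a Spearman correlation of -0.0088 over the 12570 tested genes with a known length. Both list calls were lost with an estimated correlation (adjusted p = 0.932 and 0.949). For the muscle list, dependence on single libraries may account for the call: its adjusted p rose to as much as 0.389 with 1 library left out, over a range of 1.19e-09 to 0.949 across all alternatives, and HLB01 replicate 3 lay above the Control mean. No biological explanation was tested for these lists.

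The lower vitellogenins had a mean log2 fold change of -0.37. A smaller share of intestinal RNA would lower other intestinal genes as well, but the mean log2 fold change of 13 intestine markers was -0.033 ± 0.043 (SE over markers) and the lowest of them was -0.26. The 26 oocyte and germline markers had a mean of 0.0047 ± 0.0097 (SE over markers, which are not independent), with no sign of less of that tissue. Between libraries, their mean varied with an SD of 0.042 in Control and 0.048 in HLB01. Since vitellogenins are made in the intestine, these values do not decide a cause of the lower vitellogenins. A difference in stage or reproductive state cannot be told apart from HLB01, since sperm and early embryo markers had means of -0.15 ± 0.18 and -0.14 ± 0.14 (SE between libraries). An effect of HLB01 on yolk protein expression was not tested apart from these, nor were differences in age or feeding, which would need animals staged at harvest.

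The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 50 changed genes and the highest other split gave 5, so that 1 split, the real one, reached the count. For lists the real split gave 13 and the highest other 18, and 3 of the 10 splits, the real one included, gave at least as many lists as the real one. Every other split mixes libraries of both groups. A difference between the groups would add to the spread in such splits, so their counts do not show what data with no change would give.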
